A study of Mus musculus with 11 samples.

How the data were processed

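Blood of 8-week-old female C57/BL6 mice was measured on 11 Illumina MouseWG-6 v2 bead arrays: 3 of sham mice at 6 h and 4 of PCI mice at each of 6 h and 24 h. Per the labels, blood was taken into PAXgene reagent, globin RNA was removed with GLOBINclear, and biotinylated cRNA was hybridized and read with BeadStudio 3.23. The intensity values were deposited by the authors as probe signal per array, per the file headers not normalized between arrays, and no value lay near or below 0, so background had not been subtracted. The detection p-values were deposited beside each signal by the authors; per the file headers each belongs to a probe on an array, and it gives the share of negative control probes as bright as the probe. The log2 values of the second table were normalized between arrays by the authors with a method that the labels do not state. In that table each array had a Spearman correlation of 1 with its deposited signal, and Sham 6 h replicate 2 equalled log2 of its signal. The number of arrays limits the precision, and the 5th percentile of the signal ran from 93.1 to 148.9.

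Probes were assigned to genes by the identifiers in the platform annotation. Of 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 were not listed. The deposited signal was corrected for background with limma 3.58.1 (normexp, with the background estimated from the detection p-values, because control probes were not used here), an offset of 16 was added, and arrays were quantile normalized on the log2 scale in R 4.3.3 (statmod 1.5.0 was loaded beside limma). Probes with a detection p under 0.05 on at least 3 arrays were kept (19722, of which 16345 had a gene symbol), and each of 10547 genes was represented by its brightest probe. Of 28 named gene values that passed, 15 had more than 1 probe, and 0 had a probe of opposite sign.

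A linear model of the 3 group means was fitted with limma to all 11 arrays, and 3 comparisons were tested with its moderated test, with Benjamini-Hochberg adjustment over the 10547 genes and a threshold of 0.05. For a gene detected on no array of a group, the fold was given as a bound against the detection level. Gene lists (41, holding 814 entries, of which 738 matched a probe and 666 were measured) were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with the rotation test fry, and adjusted over the 41 lists. The one-direction form of fry called 4, 0 and 0 lists in the order PCI 6 h against sham, PCI 24 h against sham and PCI 24 h against PCI 6 h, and its form for either direction called 15, 0 and 8. Median, mean and test differed in sign in 6, 3 and 2 lists, of which 0 were called. An exact two-sided permutation test of the list medians per array was added after the results were seen.

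The comparisons, lists, thresholds and the rule for named genes were fixed before the data were examined. The rule named the 8 genes with the largest positive and the 8 with the largest negative log2 fold change among those that passed without overlap between groups, the 3 members with the largest absolute change of each called list and 1 member of each other list, and a fixed set of cytokine, cell marker and reference genes. Of that set, Ly6g, Cd79a and Hbb-b1 were not measured after the filter. Apoa1 fell outside the rule and was chosen after its values were seen.

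The pipeline was tested on simulated data, in which each gene had its sham mean and independent normal noise of its moderated variance, with 50 genes changed per size in 10 runs. Arrays that differ from their group in many genes at once, as here, are not part of that simulation. A log2 change of 2 was recovered in 79.2% of genes in PCI 6 h against sham, 79.0% in PCI 24 h against sham and 84.8% between the PCI times, and a change of 1 in 10.6%, 13.4% and 18.6%. The false share among calls was 4.56%, 5.13% and 4.97%. For lists, a list of independent genes shifted by 1 was called in 20 of 20 runs, with 6 calls of unshifted lists in all, but shuffling the real residuals over arrays gave 15.1 called lists per run on average with the preset correlation, so its calls are given with the estimated correlation beside them. The correlation that a shared sham group produces was obtained from 100 simulations of unchanged groups.

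Alternatives were other background corrections, normalizations, filters, offsets and probe summaries, the deposited log2 values, fits of 2 groups, array weights, other variance priors and thresholds, the replicate number as a block, other list tests, and leaving out each array in turn. Those added after the data were seen left out 2 or 5 arrays or added a covariate. The chip of each array was not used here, so no chip block was fitted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.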

Results

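Whole-blood RNA of 8-week-old female C57/BL6 mice was measured on Illumina mouse whole-genome BeadChips, on which each probe reports the brightness of labelled RNA bound to it. Mice received 200 µl of a human faeces suspension into the peritoneal cavity, a model called peritoneal contamination and infection (PCI), or 200 µl of saline (sham). There were 11 arrays: 3 of sham mice at 6 h, 4 of PCI mice at 6 h and 4 of PCI mice at 24 h. No sham group at 24 h was analysed here, so every comparison of PCI 24 h with sham also spans the time between 6 h and 24 h. The arrays detected between 15158 and 18681 of 45281 probes, and 10547 genes were tested. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.34 against sham and 0.32 between the PCI times. The labels number the replicates of each group but do not say that each came from its own mouse, so p-values measure the spread between these samples, which may partly be technical.

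The first question was what the infection had changed in blood at 6 h. Genes that rose included the interferon-induced Cxcl10, Oasl1, Gbp2 and Ifit3 and Ifng, the gene of interferon gamma. Genes that fell included Tppp3 and S1pr5. Cxcl10, an interferon-induced chemokine that attracts T cells, rose 16.8-fold, from a mean log2 signal of 5.54 ± 0.99 (SD, n = 3, detected on 2 sham arrays) to 9.61 ± 0.72 (SD, n = 4). Ifng rose 11.4-fold, from 5.54 ± 0.51 (SD, n = 3, detected on 2 arrays) to 9.05 ± 0.85 (SD, n = 4). Tppp3, which encodes a tubulin-binding protein, fell 6.15-fold, from 7.45 ± 0.29 (SD, n = 3) to 4.83 ± 0.48 (SD, n = 4), where it was detected on 1 array. S1pr5, a sphingosine phosphate receptor of natural killer cells and patrolling monocytes, fell 4.76-fold, from 7.21 ± 0.36 (SD, n = 3) to 4.96 ± 0.28 (SD, n = 4, detected on 1 array).

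Among the 16 genes named by the rule fixed in advance, the others that rose were Ccrl2, an atypical chemokine receptor (16.6-fold, detected on 1 of 3 sham arrays), and Plscr1, an interferon-induced membrane protein (13.6-fold). Oasl1, of the oligoadenylate synthetase family, rose by a log2 fold change of 3.59. Gbp2, an interferon-inducible GTPase, rose 8.81-fold, Ifit3, an interferon-induced antiviral protein, 8.50-fold and Tnfrsf9, a costimulatory receptor of activated lymphocytes, 8.29-fold (detected on 1 of 3 sham arrays). The other genes that fell were Ptpro, a receptor tyrosine phosphatase (7.74-fold), B3gnt8, a glycosyltransferase (6.36-fold, detected on 3 of 4 PCI 6 h arrays), and Lat2, an adaptor of immune receptor signalling (4.16-fold). Mapre2 fell 3.82-fold, Vav2, a guanine nucleotide exchange factor, 3.79-fold and Kank3 3.78-fold (detected on 1 PCI 6 h array). Their limma adjusted p lay between 0.045 and 0.049. In all, 41 genes passed, 29 higher and 12 lower in PCI 6 h, and over all genes tested the arrays of both groups did not overlap in 15.8%, where chance gives 5.71%. At an unadjusted p under 0.05 there were 1682 genes, 700 higher and 982 lower, where 527 would be reached by chance on average. Among 35 splits of these arrays the highest other gave 1386.

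**Figure D1:**
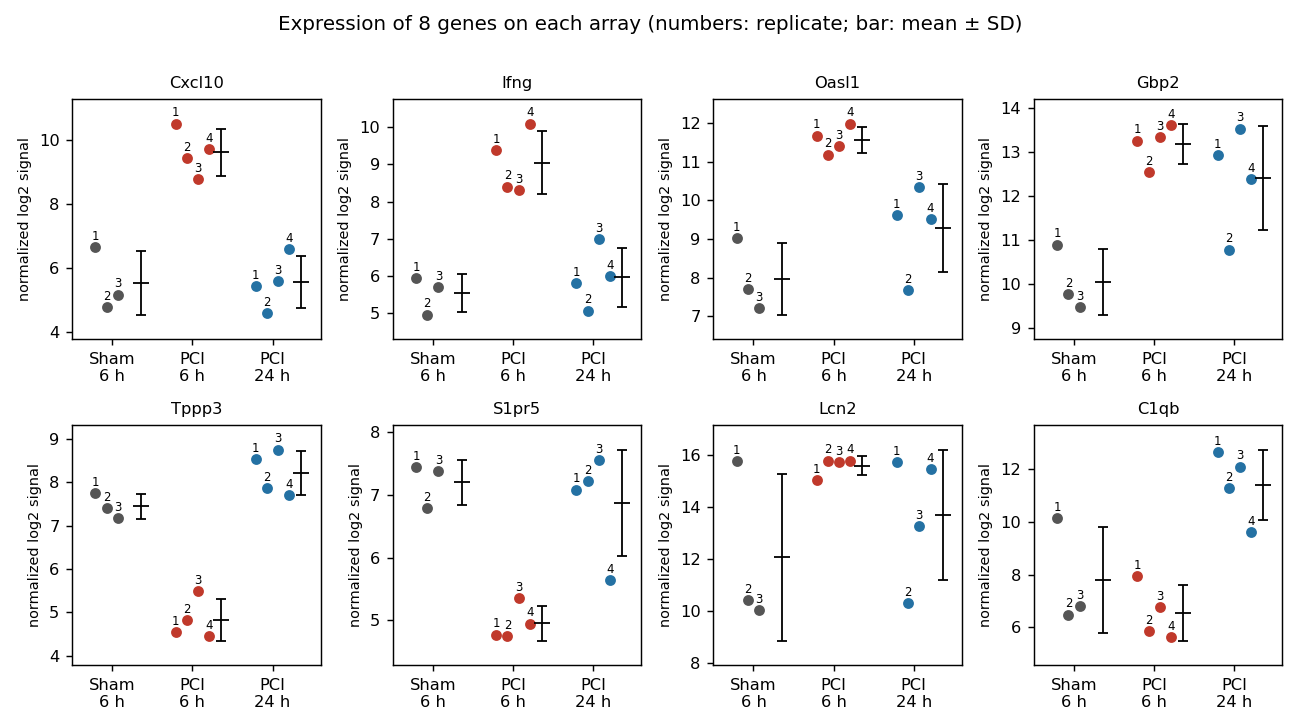
Normalized log2 signal of 8 genes on each array, with the replicate number above each point and the group mean ± SD as a bar. In PCI 6 h, Cxcl10 (mean 9.61), Ifng (9.05), Oasl1 (11.57) and Gbp2 (13.19) lie above every sham array and Tppp3 (4.83) and S1pr5 (4.96) below; Lcn2 and C1qb differ widely between arrays of one group.

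Of the 41 gene lists, 20 were shifted at 6 h with camera at a preset inter-gene correlation, 16 up and 4 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.113. The type I interferon response rose as a list, with a median log2 fold change of 1.58 (adjusted p = 1.3e-14, and adjusted p = 0.208 with an estimated correlation): 5 of its 24 measured members rose, none fell, and 14 rose when adjusted over the list alone. Interferon gamma inducible GTPases and related genes had a median of 1.20 (adjusted p = 1.47e-09, and adjusted p = 0.113 with an estimated correlation), with 1 of 13 members up and 7 adjusted over the list alone. The list medians of both lay higher on all 4 PCI 6 h arrays than on all 3 sham arrays, which gave an exact two-sided permutation p of 0.0286, the smallest that 35 splits allow, and 0.146 after adjustment over the 41 lists. Gene values of members that did not pass were 2.90 for Mx2 (adjusted p = 0.062) and 2.17 for Gbp7 (adjusted p = 0.145), both as log2 fold changes.

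Inflammatory lists were also shifted upward at 6 h. NF-kB targets and feedback genes had a median of 1.60 (adjusted p = 1.37e-13, and adjusted p = 0.217 with an estimated correlation), with 0 of 17 members past the test over all genes and 14 adjusted over the list alone. The log2 fold changes of Tnfaip3 and Gadd45b were 3.09 and 2.90 (adjusted p = 0.0712 and 0.0708). Proinflammatory cytokines and growth factors had a median of 0.89 (adjusted p = 5.17e-08, and adjusted p = 0.113 with an estimated correlation), with Ifng as the 1 member of 15 that rose and 5 members adjusted over the list alone. Chemokines had a median of 2.10 (adjusted p = 0.000104, and adjusted p = 0.553 with an estimated correlation), with Cxcl10 up over all genes and 6 of 18 members adjusted over the list alone. Ccl4 had a log2 fold change of 4.47 (adjusted p = 0.0592), Ccl3 5.02 (adjusted p = 0.107) and Cxcl2 6.08 (adjusted p = 0.146). Immediate early genes had a median of 1.06 (adjusted p = 1.81e-06, and adjusted p = 0.256 with an estimated correlation) and anti-inflammatory and checkpoint genes 0.75 (adjusted p = 8.72e-05, and adjusted p = 0.446 with an estimated correlation); adjusted over the list alone, 4 of 12 and 9 of 21 members rose and 1 checkpoint gene fell. For the NF-kB, cytokine, immediate early and checkpoint lists the arrays of both groups did not overlap either (exact two-sided permutation p = 0.0286, and 0.146 adjusted over the 41 lists). The fixed cytokine genes gave log2 fold changes of 2.13 for Tnf (adjusted p = 0.185), 3.18 for Il10 (adjusted p = 0.207) and 0.82 for Il1b (adjusted p = 0.524). Il10 was detected on 1 sham array. Il6 was detected on 2 PCI 6 h arrays and no sham array, which puts it at least 1.32-fold higher (adjusted p = 0.403).

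Neutrophil transcripts were spread widely within the sham group. The list of immature neutrophil and granule proteins had a median of 1.94 (adjusted p = 1.16e-08, and adjusted p = 0.474 with an estimated correlation) and mature neutrophil markers 1.71 (adjusted p = 3.82e-08, and adjusted p = 0.474 with an estimated correlation). None of their 21 and 18 members passed over all genes, and 13 and 5 rose adjusted over the list alone, where 1 immature member fell. Ngp, of the neutrophil granules, had means of 14.31 ± 0.89 (SD, n = 4) in PCI 6 h and 7.84 ± 3.55 (SD, n = 3, detected on 2 arrays) in sham (adjusted p = 0.132), and Ltf, the lactoferrin gene, had a log2 fold change of 6.24 (adjusted p = 0.0708). Lcn2, a siderophore-binding granule protein, read 15.78 on Sham 6 h replicate 1 against 10.41 and 10.04 on the other sham arrays, and between 15.03 and 15.79 on the PCI 6 h arrays (adjusted p = 0.25). S100a8 and S100a9 had log2 fold changes of 0.73 and 0.89 (adjusted p = 0.351 and 0.22).

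MHC class II and B cell lists lay lower at 6 h. MHC class II presentation fell as a list, with a median of −1.64 and all 10 members negative (adjusted p = 3.35e-05, and adjusted p = 0.553 with an estimated correlation). None passed over all genes, 3 fell adjusted over the list alone, and the arrays of both groups did not overlap (exact two-sided permutation p = 0.0286, and 0.146 adjusted over the 41 lists). The gap was small, with a list median of −1.38 on Sham 6 h replicate 1 and −1.41 on the nearest PCI 6 h array. H2-DMb1, which helps load peptides, had a log2 fold change of −2.15 (adjusted p = 0.0971). B cell markers had a median of −0.96, with all 16 members negative and none past the test (adjusted p = 0.00539, and adjusted p = 0.697 with an estimated correlation). That call ended without Sham 6 h replicate 2 (adjusted p = 0.284) or replicate 3 (adjusted p = 0.0864), with the plasma protein list mean of each array as a covariate (median −0.27, adjusted p = 0.432) and with the background level as one (median −0.64, adjusted p = 0.148). Monocyte and macrophage markers had a median of −0.86, with 10 of 11 members negative (adjusted p = 0.0143, and adjusted p = 0.635 with an estimated correlation). It lost the call without Sham 6 h replicate 1 (adjusted p = 0.422) or PCI 6 h replicate 1 (adjusted p = 0.058), and with array weights (median −0.45, adjusted p = 0.0715). It also lost it without the 5 arrays with the highest plasma protein list medians (median −0.14, adjusted p = 0.408), which left 2 arrays per group. Within that list, Csf1r, the receptor of macrophage colony-stimulating factor, had a log2 fold change of −2.41 (adjusted p = 0.0898). Ace, the angiotensin-converting enzyme, was detected on all 3 sham arrays and no PCI 6 h array, at least 5.74-fold lower (adjusted p = 0.105), and Cx3cr1, the fractalkine receptor, had a log2 fold change of −2.92 (adjusted p = 0.126). Cd14, a coreceptor for endotoxin, had a log2 fold change of 4.28 (adjusted p = 0.134). T cell markers and NK and cytotoxic cell markers had medians of −0.22 and 0.11 (adjusted p = 0.513 and 0.445), and Cd3e had a log2 fold change of −0.21 (adjusted p = 0.902).

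Among metabolic and other lists at 6 h, all 17 members of the tricarboxylic acid cycle list were negative, with a median of −0.51 and none past the test (adjusted p = 0.000668, and adjusted p = 0.474 with an estimated correlation). On the sham arrays the list median was −0.26, −0.18 and, on replicate 3, 0.46; that array also had high adipocyte genes (median 9.06) and Ucp1 of brown fat (10.57). Cell cycle and proliferation genes had a median of 0.39 (adjusted p = 0.000102, and adjusted p = 0.591 with an estimated correlation). Without the 5 arrays with the highest plasma protein list medians that list lost its camera call (adjusted p = 0.0624), though its median was 0.476. Apoptosis regulators had a median of 0.79 (adjusted p = 0.00539, and adjusted p = 0.217 with an estimated correlation). Fas, a death receptor, had a log2 fold change of 2.03 (adjusted p = 0.144). Oxidative phosphorylation, glycolysis, cytosolic ribosomal proteins and globins did not pass (adjusted p = 0.846, 0.953, 0.171 and 0.634), but without Sham 6 h replicate 2 oxidative phosphorylation was called lower (median −0.30, adjusted p = 0.00298). Gapdh and Actb had log2 fold changes of −0.02 and 0.06 (adjusted p = 0.984 and 0.943), and the sign of Gapdh turned with the deposited values, loess, and scaling to the 75th percentile or to reference genes.

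Transcripts of plasma proteins made in the liver differed widely between arrays of one group. The list of hepatocyte and plasma acute phase proteins had a median log2 fold change of 2.86 at 6 h (adjusted p = 8.72e-05, and adjusted p = 0.635 with an estimated correlation), with all 16 members positive and none past the test. Relative to the sham mean, the list median was 7.30 and 5.48 on PCI 6 h replicates 1 and 2 and −0.40 and −0.35 on replicates 3 and 4. On PCI 24 h replicates 1 and 4 it was 5.35 and 6.19, against −0.43 and −0.82 on replicates 2 and 3, and on Sham 6 h replicate 1 it was 1.97 against −0.90 and −0.81. Apoa1, the main protein of high-density lipoprotein, read 13.76 and 11.12 on PCI 6 h replicates 1 and 2 and 4.64 and 4.50 on replicates 3 and 4. Orm1, an acute phase protein, was high on all 4 PCI 6 h arrays, from 11.91 to 13.66, against 10.31, 4.45 and 6.52 on the sham arrays (adjusted p = 0.207).

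**Figure D2:**
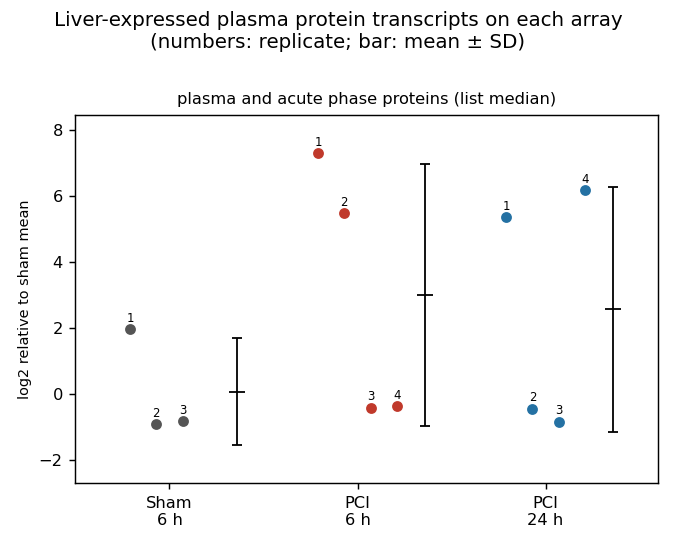
Median log2 signal of the hepatocyte and plasma acute phase protein list on each array, relative to the sham mean, with the replicate number above each point and the group mean ± SD as a bar. PCI 6 h replicates 1 and 2 (7.30 and 5.48) and PCI 24 h replicates 1 and 4 (5.35 and 6.19) stand far above the other arrays, of which Sham 6 h replicate 1 is the highest (1.97).

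The count of 41 genes depended on single arrays. It was 0 without Sham 6 h replicate 3, PCI 6 h replicate 2, PCI 6 h replicate 4, PCI 24 h replicate 1 or PCI 24 h replicate 3, 1 without Sham 6 h replicate 2 or PCI 6 h replicate 3, and 2 without PCI 6 h replicate 1, while it was 145 without Sham 6 h replicate 1, 71 without PCI 24 h replicate 2 and 262 without PCI 24 h replicate 4. With Sham 6 h replicate 1 and PCI 24 h replicate 2 both left out it was 397, all 41 among them.

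The next question was which differences from sham were present at 24 h. No gene passed the test in PCI 24 h against Sham 6 h: limma called 0 genes, and the smallest adjusted p was 0.978. An unadjusted p under 0.05 was found for 350 genes, where 527 would be reached by chance on average. Of 35 splits of these arrays, 23 reached that count. The C1q genes, which encode the first component of complement and are made by macrophages, had log2 fold changes of 3.62 ± 0.93 (SE) for C1qb, 3.28 ± 0.98 (SE) for C1qc and 2.90 ± 0.70 (SE) for C1qa, all with an adjusted p of 0.978. C1qb had a mean log2 signal of 11.42 ± 1.33 (SD, n = 4) in PCI 24 h and 7.81 ± 2.03 (SD, n = 3) in sham. Isg15, an interferon-induced modifier protein, had a log2 fold change of 2.89 and Tgtp1, an interferon-inducible GTPase, of 2.50, and neither overlapped between the groups (adjusted p = 0.978 for both). Over all genes tested 3.43% did not overlap, where chance gives 5.71%. The fixed genes Tnf, Il10, Lcn2 and Csf1r had log2 fold changes of 0.73, 1.44, 1.62 and −0.23 (adjusted p between 0.978 and 0.985).

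As lists, 19 of 41 were shifted at 24 h with the preset correlation, 13 up and 6 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.548. Cell cycle and proliferation rose, with a median of 0.64 and 18 of 21 members positive (adjusted p = 1.16e-09, and adjusted p = 0.548 with an estimated correlation). Cdk1 and Kif11, of mitosis, had log2 fold changes of 1.46 and 1.45. Complement and Fc receptors rose, with a median of 0.89, 12 of 13 members positive and the 3 C1q genes past the test adjusted over the list alone (adjusted p = 4.17e-06, and adjusted p = 0.548 with an estimated correlation). Proteasome genes were positive in all 26 members with a median of 0.32 (adjusted p = 4.9e-05, and adjusted p = 0.548 with an estimated correlation). MHC class II presentation fell, with a median of −1.36 and all 10 members negative (adjusted p = 6.67e-08, and adjusted p = 0.548 with an estimated correlation). B cell markers fell, with a median of −1.04 and all 16 negative (adjusted p = 1.36e-06). T cell markers fell, with a median of −0.80 and 18 of 20 negative (adjusted p = 3.98e-06), and platelet and megakaryocyte markers with −0.58 and 15 of 17 negative (adjusted p = 3.21e-05). With an estimated correlation the adjusted p was 0.548 for the B cell, T cell and platelet lists alike. The exact two-sided permutation p of the list medians was 0.0857 for cell cycle, 0.286 for complement and 0.229 for proteasome and MHC class II. It was 0.343 for B cell, 0.371 for T cell and 0.2 for platelet markers, and 0.799 for each of these lists after adjustment. Cd74, the invariant chain of MHC class II, had a log2 fold change of −1.46, Cd3g, of the T cell receptor complex, −1.29 and Ppbp, a platelet chemokine, −0.74 (adjusted p = 0.978 for each).

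Neutrophil and interferon lists were also shifted upward at 24 h with the preset correlation. Immature neutrophil and granule proteins had a median of 0.92 (adjusted p = 4.57e-05, and adjusted p = 0.548 with an estimated correlation), and interferon gamma inducible genes 0.44 (adjusted p = 0.00281, and adjusted p = 0.548 with an estimated correlation). The type I interferon response had a median of 0.55 (adjusted p = 0.000293, and adjusted p = 0.548 with an estimated correlation) and lost the call without Sham 6 h replicate 3 (median 0.30, adjusted p = 0.0718) or with the background level as a covariate (median 0.16, adjusted p = 0.0886). The hepatocyte and plasma protein list had a median of 2.43 (adjusted p = 5.81e-05, and adjusted p = 0.629 with an estimated correlation), carried by PCI 24 h replicates 1 and 4. In the exact two-sided permutation test of list medians, p was 0.343 for the immature neutrophil list, 0.371 for type I interferon and 0.171 for interferon gamma. Only 1 of the 41 lists had a p under 0.05. This was the tricarboxylic acid cycle list, lower on all 4 PCI 24 h arrays than on all sham arrays (exact two-sided permutation p = 0.0286, and 0.799 adjusted over the 41 lists). Its camera call (median −0.32, adjusted p = 7.21e-05, and adjusted p = 0.548 with an estimated correlation) ended without Sham 6 h replicate 3 (median −0.11, adjusted p = 0.115), the array with high adipocyte genes and Ucp1 (10.57).

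Across 10547 genes, PCI 24 h replicate 2 correlated best with Sham 6 h replicate 3 (r = 0.966), and Sham 6 h replicate 1 correlated best with PCI 24 h replicate 1 (r = 0.961); genes are not independent replicates. Without both arrays, 212 genes passed at 24 h, 95 higher and 117 lower, a choice made after their values were seen and one that raises the count by its construction. That fit took its spread from the PCI 6 h arrays as well. In a fit of the remaining sham and PCI 24 h arrays alone, 0 genes passed. Leaving out any other single array gave 0 genes, and leaving out Sham 6 h replicate 1 alone gave 1.

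**Figure D3:**
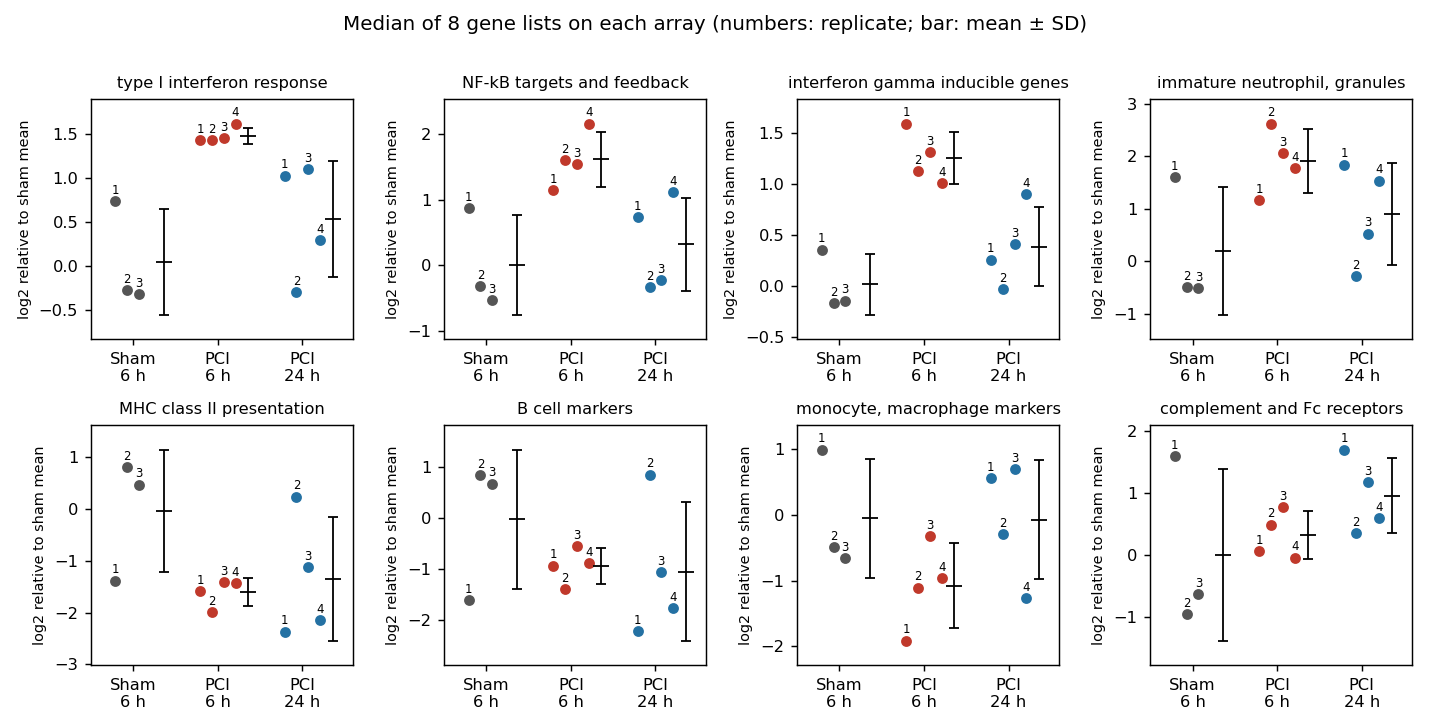
Median log2 signal of 8 gene lists on each array, relative to the sham mean, with the replicate number above each point and the group mean ± SD as a bar. The type I interferon, NF-kB and interferon gamma lists lie higher on all 4 PCI 6 h arrays (means 1.48, 1.61 and 1.26) than on all sham arrays, whereas for the neutrophil, MHC class II and B cell lists Sham 6 h replicate 1 lies among the PCI arrays and PCI 24 h replicate 2 beside the other sham arrays.

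The last comparison asked how infected blood differed between 24 h and 6 h, with the spread taken from all 11 arrays, sham included. Without a sham group at 24 h, effects of infection and of time could not be separated here. The interferon-induced genes Cxcl10, Mx1, Stat2 and Ifit2 fell, and Tppp3 rose. Cxcl10 fell 16.5-fold, to 5.56 ± 0.81 (SD, n = 4) (adjusted p = 0.0136), Ifng 8.46-fold, to 5.97 ± 0.79 (SD, n = 4) (adjusted p = 0.0392), and Mx1, an antiviral GTPase, 6.73-fold (adjusted p = 0.0176). Each of these was detected on 3 of 4 PCI 24 h arrays. Tppp3 rose 10.4-fold, to 8.21 ± 0.51 (SD, n = 4) (adjusted p = 0.002), a fold against a level near background, as 1 of 4 PCI 6 h arrays detected it. Rras, a small GTPase, rose 5.38-fold, from 6.93 ± 0.24 (SD, n = 4) to 9.36 ± 0.73 (SD, n = 4) (adjusted p = 0.0392). Tmem86a rose 2.57-fold and Poglut2, a protein glucosyltransferase, 2.40-fold (adjusted p = 0.0392 for both); Poglut2 was detected on 3 of 4 PCI 6 h arrays. Stat2, a signal transducer of type I interferon, fell 4.27-fold, Ifit2 4.13-fold, Adss, of purine synthesis, 3.95-fold, and Helz2 and Parp10 3.69-fold each (adjusted p between 0.00897 and 0.0392).

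In all, 15 genes passed, 4 higher and 11 lower at 24 h, and over all genes tested the arrays of both times did not overlap in 7.41%, where chance gives 2.86%. There were 1262 genes with an unadjusted p under 0.05, 768 higher and 494 lower, where 527 would be reached by chance on average. Of 35 splits of the PCI arrays, 3 reached that count, the real one among them, with a highest other of 1517. Of the genes that passed after adjustment, 1 was higher and 6 lower with scaling to the 75th percentile, and 8 were higher and 56 lower with centring on reference genes. The count ranged from 1 to 342 when single arrays were left out: it was 73 without Sham 6 h replicate 1, 7 without Sham 6 h replicate 2 and 9 without Sham 6 h replicate 3. Without PCI 6 h replicates 1 to 4 in turn it was 6, 2, 3 and 1, and without PCI 24 h replicates 1 to 4 in turn 1, 4, 1 and 342. Tppp3 passed in each of these 11 fits, with log2 fold changes from 3.20 to 3.60.

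Of the lists, 17 of 41 differed between 24 h and 6 h with the preset correlation, 4 up and 13 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.195. NF-kB targets and feedback genes fell as a list, with a median of −1.37, all 17 members negative, none past the test over all genes and 14 adjusted over the list alone (adjusted p = 3.55e-14, and adjusted p = 0.222 with an estimated correlation). The type I interferon response had a median of −0.90, with 3 of 24 members lower and 11 adjusted over the list alone (adjusted p = 3.51e-09, and adjusted p = 0.293 with an estimated correlation). Proinflammatory cytokines had −0.93 (adjusted p = 3.91e-08, and adjusted p = 0.195 with an estimated correlation), interferon gamma inducible genes −0.78 (adjusted p = 2.4e-06, and adjusted p = 0.222 with an estimated correlation) and immediate early genes −1.05 (adjusted p = 1.73e-06, and adjusted p = 0.283 with an estimated correlation). Apart from immediate early genes, the arrays of both times did not overlap for these lists (exact two-sided permutation p = 0.0286, the smallest possible, and 0.195 adjusted over the 41 lists). Mature neutrophil markers had a median of −1.07 (adjusted p = 1.03e-05, and adjusted p = 0.737 with an estimated correlation).

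Monocyte and macrophage markers had a median of 0.91 between the times, with 10 of 11 members positive and 3 past the test adjusted over the list alone (adjusted p = 0.00716, and adjusted p = 0.737 with an estimated correlation). The call ended without PCI 6 h replicate 1 (adjusted p = 0.0601). Csf1r had a log2 fold change of 2.18 (adjusted p = 0.113), and Ace, which no PCI 6 h array detected and 3 PCI 24 h arrays did, was at least 5.24-fold higher (adjusted p = 0.111). The C1q genes had log2 fold changes of 4.87 for C1qb (adjusted p = 0.0508), 4.55 for C1qc (adjusted p = 0.0688) and 3.08 for C1qa (adjusted p = 0.0767), which 4, 2 and 1 of the PCI 6 h arrays detected. Their list, complement and Fc receptors, had a median of 0.25 (adjusted p = 0.0363, and adjusted p = 0.737 with an estimated correlation) and lost the call without PCI 6 h replicate 1 or 4 or PCI 24 h replicate 1 or 3 (adjusted p = 0.0529, 0.0574, 0.109 and 0.0913). It also lost the call with the deposited values, without background correction and with camera on ranks (adjusted p = 0.0692, 0.0638 and 0.192). Heat shock genes rose as a list, with a median of 0.38, 9 of 10 members positive and 1 past the test adjusted over the list alone (adjusted p = 0.0148, and adjusted p = 0.513 with an estimated correlation). The call ended without PCI 6 h replicate 3 (adjusted p = 0.0546) or PCI 24 h replicate 4 (adjusted p = 0.0523). Hsph1, a chaperone and the member that passed over the list alone, had a log2 fold change of 1.22 (adjusted p = 0.132 over all genes). The hepatocyte and plasma protein list did not differ in the test (median −0.42, adjusted p = 0.222), with 2 arrays of each time carrying these transcripts.

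Because both comparisons with sham share the same 3 sham arrays, their fold changes are tied by chance. Across genes the correlation of the 2 sets of log2 fold changes was 0.63, against 0.572 in simulated unchanged groups, and the covariance was 0.225 against 0.136. The same sign was found for 71.2% of genes, against 69.4% in the simulation. The simulated noise was independent between genes, whereas genes here vary together. The simulation therefore cannot show whether these excesses go beyond chance. No gene was called at both times, where independent lists would also give 0. The 41 genes called at 6 h had a median log2 fold change at 24 h of 0.30 in the direction of 6 h, against 2.02 at 6 h, and their choice against the same sham arrays favours that direction. All 41 moved back between the times, and 12 of the 41 were among the 15 called between 24 h and 6 h; genes chosen for a high or low value at 6 h move back partly by their selection.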

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

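The weighed tests of liver transcripts, of the arrays that resemble another group and of monocyte genes were chosen only after the results were seen, whereas the search for distant samples, the comparison between PCI times and the splits of the samples were planned.

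Transcripts of liver proteins stood high on PCI 6 h replicates 1 and 2 and PCI 24 h replicates 1 and 4. Against induction in the blood cells of all infected mice, only these 4 of 8 infected arrays had a plasma protein list median above the highest sham array. Liver RNA in the blood sample may account for the pattern, since the median of 10 hepatocyte genes outside the plasma protein list was at least 1.62 log2 higher on each of the 4 arrays than on any other array (range 6.91 to 9.56 against 4.59 to 5.29). Whether such RNA was released in infected mice or entered at sampling cannot be told apart. An exact two-sided permutation test of 8 infected against 3 sham arrays gave p = 0.267, but neither outcome of that test would separate the 2 sources.

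Sham 6 h replicate 1 and PCI 24 h replicate 2 each resembled the other group. On 505 genes with an unadjusted p under 0.01 between the other 2 sham and 3 other PCI 24 h arrays, of which 0 passed adjustment in that fit, they lay at 0.83 and 0.116 on a scale from sham (0) to PCI 24 h (1). The sham array stayed at 0.809 or more with the deposited values and without background correction. Both settings also bring the arrays to a similar level, and other scalings were not applied to this scale. The normalization as a cause was therefore hardly tested. Exchanged labels could give these positions. The mean of C1qa, C1qb and C1qc on Sham 6 h replicate 1 was 8.53, against 5.27 and 6.07 on the other sham arrays. It was 11.08, 10.7 and 7.89 on PCI 24 h replicates 1, 3 and 4. Yet on PCI 24 h replicate 2 that mean was 4.197 log2 above the other 2 sham arrays, as may be in an infected mouse with a small response. The C1q genes had stood out in a comparison that included PCI 24 h replicate 2, so their height there follows partly from their choice. That array also had the highest median of tissue macrophage genes (6.82, against 4.66 to 6.22 on the others), and a link to C1q was not tested. Exchanged labels cannot be told apart from an inflamed sham mouse and a small response. On both arrays in question C1q lay above the other 2 sham arrays, and 6 h infected arrays (0.709 to 0.835) lay where the sham array did.

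Nonclassical monocyte genes were chosen after Csf1r, Ace and Cx3cr1 had been seen. The group mean of their list median per array differed by −1.10 log2 in PCI 6 h against sham (exact two-sided permutation p = 0.0571, n = 4 and 3). In PCI 24 h against PCI 6 h it differed by 1.05 (exact two-sided permutation p = 0.0857). The list median was 7.53 and 7.45 on PCI 6 h replicates 1 and 2, which carry liver transcripts, and 8.07 and 8.26 on replicates 3 and 4. It was 9.77 on the doubted Sham 6 h replicate 1 and 8.21 and 8.8 on the other sham arrays, so much of the difference rests on those arrays. Fewer nonclassical monocytes in blood may be one explanation and dilution by neutrophils another, for which the difference from the NK and T cell lists was −1.002 (exact two-sided permutation p = 0.0571). Classical monocyte genes differed by 0.08 (exact two-sided permutation p = 0.857). The 2 explanations cannot be told apart, because no test passed at this number of arrays.

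In PCI 6 h against sham, 1 of 35 splits of the 7 arrays, the real one, gave as many as 41 genes, and the highest other gave 2. That is the smallest share that 35 splits allow and was not adjusted for the other counts examined. It makes chance less likely for this count without excluding it. Chance cannot be excluded for the 20 lists either, which 11 splits reached, with a highest other of 25. For PCI 24 h against sham the real count was 0, which all 35 splits reached. The highest other gave 665 genes, from exchanging Sham 6 h replicate 1 and PCI 24 h replicate 2, which points to a structure of the samples. For its 19 lists chance cannot be excluded (10 splits, highest other 26). Between the PCI times chance cannot be excluded for the 15 genes, which 3 of 35 splits reached, or for the 17 lists (8 splits, highest other 18). The highest other split gave 150 genes and set the 4 arrays with liver transcripts against the rest, again a structure of the samples.

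A single array was flagged, by its gap from the other 3 relative to the range of its group, in 22 of 458 groups tested. That is about the 5% that chance gives for independent tests, but genes and lists vary together. Only the PCI groups were searched, so Sham 6 h replicate 1 was not examined. Nor is the rule suited to 2 arrays of a group that stand out together, as with the liver transcripts. The rate therefore cannot show whether arrays are outlying. The rule also flags small gaps in tight groups, such as the type I interferon list in PCI 6 h (1.61, against 1.42 to 1.45 on the others). In PCI 6 h the flagged arrays were replicate 1 for Aurkb (4.99), Ifit2 (11.37), Lcn2 (15.03), Mrgpra2b (11.97) and the inflammasome and coagulation lists (−0.51 and −0.30). Replicate 2 stood apart for Clec4e (11.90), Clec7a (8.37) and Rpl22 (7.40), and replicate 4 for the type I interferon list (1.61). In PCI 24 h these were replicate 1 for Alas2 (15.16) and the fatty acid oxidation list (−0.10), and replicate 2 for S100a9 (14.25). Replicate 3 stood apart for Acadm (8.80), Kel (11.65) and the MHC class I and heat shock lists (0.47 and 0.68). Replicate 4 did so for Bcl2l11 (9.76), Egr1 (12.04), Hsp90b1 (10.12), Mapre2 (6.5) and the apoptosis list (0.28).

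PCI 24 h and PCI 6 h differed in the direct test for 15 genes, a count for which chance could not be excluded. The higher genes had log2 fold changes of 3.38 for Tppp3, 2.43 for Rras, 1.36 for Tmem86a and 1.26 for Poglut2. The lower genes had −4.05 for Cxcl10, −3.08 for Ifng, −2.75 for Mx1, −2.17 for Gm12250, −2.09 for Stat2, −2.04 for Ifit2 and −1.98 for Adss. The smallest were −1.89 for Helz2, −1.88 for Parp10, −1.82 for Ndrg3 and −1.78 for Znfx1. Camera with the preset correlation called 17 lists and with an estimated correlation 0 (smallest adjusted p = 0.195). Their medians were −1.10 and −1.07 for immature and mature neutrophil genes, 0.91 for monocyte markers, −0.63 for T cell markers and −0.38 for platelet markers. Medians were −0.072 for MHC class I, −0.90 for type I interferon, −0.78 for interferon gamma inducible genes, −0.93 for cytokines, −1.37 for NF-kB targets and −0.64 for checkpoint genes. The others were −0.16 for pattern recognition receptors, 0.25 for complement and Fc receptors, 0.27 for proteasome, 0.38 for heat shock, −0.42 for apoptosis regulators and −1.05 for immediate early genes. Of the 17 calls, 9 ended when some single array was left out. Without PCI 24 h replicate 1 these were T cell markers (−0.235, adjusted p = 0.311), platelet markers (−0.143, adjusted p = 0.127), proteasome (adjusted p = 0.163), complement and Fc receptors (adjusted p = 0.109) and MHC class I (adjusted p = 0.0661). Without PCI 24 h replicate 2 they were immature neutrophil genes (adjusted p = 0.0567), pattern recognition receptors (adjusted p = 0.152) and MHC class I (adjusted p = 0.143). Without PCI 24 h replicate 3 it was complement and Fc receptors (adjusted p = 0.0913). Without PCI 24 h replicate 4 they were platelet markers (adjusted p = 0.168), proteasome (adjusted p = 0.425), heat shock (adjusted p = 0.0523) and MHC class I (adjusted p = 0.217). Leaving out PCI 6 h replicate 1 ended those of monocyte markers (adjusted p = 0.0601), complement and Fc receptors (adjusted p = 0.0529) and proteasome (adjusted p = 0.104), and replicate 2 that of platelet markers (adjusted p = 0.158). Leaving out PCI 6 h replicate 3 ended those of heat shock (adjusted p = 0.0546) and MHC class I (adjusted p = 0.271), and replicate 4 those of complement and Fc receptors (adjusted p = 0.0574), proteasome (adjusted p = 0.0727) and MHC class I (adjusted p = 0.163). The MHC class I call also ended without Sham 6 h replicate 1 (adjusted p = 0.0603) or 3 (adjusted p = 0.0511), and the proteasome call without Sham 6 h replicate 3 (adjusted p = 0.057).

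Probes without a gene symbol, which the comparisons left out, held 3 of 3377 that rose in PCI 6 h against sham and 2 that fell between 6 h and 24 h, in a fit of all probes in which 29 and 19 probes with a symbol passed.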

How the results depend on the processing

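The tests that left out 2 or 5 arrays or added a covariate were chosen after the data were seen; the others were planned. The count of 0 genes at 24 h against sham stayed at 0 under every alternative fixed in advance except leaving out 1 array, with a count of 1 without Sham 6 h replicate 1, and type I interferon, NF-kB and interferon gamma lists kept their call at 6 h at the preset correlation without any single array, but lost it with an estimated correlation (adjusted p = 0.208, 0.217 and 0.113). The one-direction form of fry called these lists and the cytokine list at 6 h (fry adjusted p = 0.0293, 0.0334, 0.0137 and 0.0168). No named gene that had passed turned its sign, while 243 values that passed under neither setting did. Dim probes limit what can be seen, as 19722 of 45281 were past the filter. The chip block was not run. The labels do not say whether replicate numbers pair the arrays. Arrays of different groups with the same number had correlations of their deviations from the group mean between −0.195 and 0.601. The cause was not tested unless stated.

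For PCI 6 h against sham (41 genes) the count was 25 with the deposited values, 3 with 75th percentile scaling, 8 with no filter (more genes tested), 25 with the mean of probes, 157 in a fit of 2 groups, 324 with array weights, 0 with the replicate block, 0 at adjusted p under 0.01 and 9 without moderation. It was 397 without the 2 doubted arrays, which raises the count by construction, 422 without the 5 arrays with the highest plasma protein list medians (the 4 with liver transcripts and Sham 6 h replicate 1, which was low in the other hepatocyte genes and is 1 of the 2 doubted arrays), 0 with the hepatocyte covariate and 0 with the background covariate. For PCI 24 h against PCI 6 h (15 genes) it was 25 with the deposited values, 7 with 75th percentile scaling, 47 with loess, 64 centred on reference genes, 34 with offset 50, 36 in a fit of 2 groups, 534 with array weights, 28 with the replicate block, 2 at adjusted p under 0.01 and 9 without moderation. It was 340 without those 5 arrays and 64 with the hepatocyte covariate. Leaving out those 5 arrays left 2 per group, so the counts of 422 and 340 rest on few arrays. PCI 6 h replicates 3 and 4, which remained, were the most alike pair of all arrays (r = 0.983). The doubted PCI 24 h replicate 2 also remained. Without the 2 doubted arrays 212 genes passed at 24 h against sham and 121 at both times, in a fit that included the PCI 6 h arrays. Without these, 0 passed at 24 h against sham. Lists called fell to 0, 0 and 0 with an estimated correlation and to 4, 0 and 0 with fry. Centring on reference genes moved the median of all genes by over 0.1, to −0.21 at 24 h against sham and −0.23 between the PCI times. Leaving out 1 array gave 0 to 262 genes at 6 h, 0 to 1 at 24 h against sham, 1 to 342 between the PCI times, and 0 to 1 at both times; lists ranged from 17 to 22, 13 to 23 and 14 to 18.

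Without Sham 6 h replicate 2 the direction of the test turned for the oxidative phosphorylation list, with medians of −0.299 at 6 h, now called lower (adjusted p = 0.00298), and −0.098 at 24 h (ranges −0.299 to 0.176 and −0.098 to 0.425), and for the ribosomal list, with −0.029 at 24 h (range −0.029 to 0.263). Without the same 5 arrays it turned for the erythroid list (−0.161) at 6 h, monocyte markers (0.729, now called higher with adjusted p = 1.02e-05 at the preset correlation) at 24 h against sham, and platelet markers (−0.047) and proteasome (−0.055) between the PCI times. These values rest on the 2 arrays per group that remained. The erythroid median at 6 h was also negative, at −0.024 (adjusted p = 0.883), without Sham 6 h replicate 1 alone or without the 2 doubted arrays (−0.024, adjusted p = 0.877). Other list medians between the PCI times changed sign while the test kept its direction: proteasome (−0.065) and complement and Fc receptors (−0.003) when centred on reference genes, complement and Fc receptors (−0.015) without those 5 arrays, and MHC class I (0.009) without PCI 24 h replicate 4. The hepatocyte covariate gave the hepatocyte list −0.247 at 6 h and 0.017 at 24 h, which follows from the covariate being that list's own mean.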

Other observations

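The levels of genes of other tissues were examined only in tests chosen after the results were seen, as were the single genes named from them, and the remaining lists were planned.

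Some genes of fat and vessel wall were high on single arrays in each group. The median of adipocyte genes was 9.06 log2 on Sham 6 h replicate 3, 7.85 on PCI 6 h replicate 1 and 6.23 on PCI 24 h replicate 4, against 4.63 to 5.94 on the others. Ucp1, the uncoupling protein of brown fat, read 10.57 on Sham 6 h replicate 3 and Adipoq, which encodes adiponectin, 9.92. Endothelial genes had a median of 8.89 on PCI 24 h replicate 4, 7.85 on Sham 6 h replicate 3 and 7.00 on PCI 6 h replicate 1, against 4.77 to 5.97 on the others. On PCI 24 h replicate 4, Cldn5, a tight junction protein, read 10.04, Flt1 9.46 and Emcn 7.39, each the highest of all arrays. Pecam1 (8.32) was the lowest of all arrays there, and Kdr (5.09) and Esam (10.9) lay within the range of the others. Of 3 exocrine pancreas genes measured, Amy2a5, an amylase, read 9.08 and 7.12 on PCI 6 h replicates 1 and 2, 7.36 and 7.69 on PCI 24 h replicates 1 and 4 and 7.93 on Sham 6 h replicate 3, against 4.32 to 5.58 on the others. Those arrays are the 4 with liver transcripts and the sham array with fat genes. Cel lay between 4.50 and 5.40 and Cela1 between 9.35 and 11.02 on all arrays. Skeletal muscle medians lay between 5.40 and 6.25, and the 1 mesothelial gene measured, Upk3b, between 4.62 and 6.98. Tissue macrophage genes had their highest median, 6.82, on PCI 24 h replicate 2, where Timd4 read 7.46, Vsig4 6.94 and Marco 6.87, but Vcam1 4.51 and Cd163 4.63; Marco read 6.89 on PCI 24 h replicate 1.

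Erythroid and energy lists were shifted in some comparisons. Erythroid markers had a median log2 fold change of 0.57 at 24 h against sham (adjusted p = 0.000348, and adjusted p = 0.548 with an estimated correlation), with 14 of 17 members positive, and lost the call without Sham 6 h replicate 1 (adjusted p = 0.433) or the 5 arrays with the highest plasma protein list medians (adjusted p = 0.174). Rhag, of the red cell membrane, had a log2 fold change of 1.77. Fatty acid oxidation genes had a median of −0.48 at 24 h against sham (adjusted p = 0.000348, and adjusted p = 0.548 with an estimated correlation), with 14 of 16 members negative, and lost the call without Sham 6 h replicate 3 (median −0.09, adjusted p = 0.313). That array, with high Ucp1 and Adipoq, had a list median of 0.88 against −0.18 and −0.48 on the other sham arrays. Cpt2 and Acadm, of mitochondrial fat oxidation, had log2 fold changes of −1.03 and −0.92. Glucocorticoid responsive genes had a median of 1.05 at 6 h (adjusted p = 0.0208, and adjusted p = 0.635 with an estimated correlation) and lost the call without Sham 6 h replicate 2 (adjusted p = 0.0873) or 3 (adjusted p = 0.0533), with the plasma protein covariate (adjusted p = 0.175) and without members shared with other lists (adjusted p = 0.179).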
